A study of Bos taurus and Bubalus kerabau with 6 samples.

How the data were processed

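The series covers longissimus muscle, the long muscle of the back, from 6 adult animals aged 12 months: 3 native cattle (Bos taurus) and 3 swamp buffalo (Bubalus kerabau). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, ribosomal RNA was removed from total RNA, and complementary DNA was made with random primers. The second strand was digested before amplification, and libraries were read as 150 bp pairs on an Illumina HiSeq. The same protocol text, given for all 6 libraries, also describes an RNase R digestion, which removes linear RNA, and does not say to which libraries it was applied. Per the submitters' processing notes, Trim Galore, TopHat2 2.0.14 and Cufflinks were used. The genome build, and whether buffalo reads were aligned to a cattle or a buffalo genome, are not given in the sources used here.

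Both deposited files describe the series as a whole. Their columns name no animal and no species. The first lists assembled transcripts with 4 columns named CNCI, CPAT, CPC and Pfam, per the file headers. CNCI, CPAT and CPC are programs that judge from sequence whether an RNA can code for a protein, and Pfam is a collection of protein domain families. Each cell repeats the transcript's identifier or holds NA, which was checked for every cell. In such tables an identifier usually marks a transcript that the tool called non-coding, but the file does not say so, and the columns are therefore called lists here. A transcript missing from all 4 lists does not appear in the file. The transcript identifiers have the form locus number, then isoform number, with the prefix MSTRG. That prefix is the default of StringTie's merge step, a tool the processing notes do not name.

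The second file holds pairs of genes, the cattle protein matched to each gene, and a deposited score per pair, with no header. The scores are whole numbers, and the protein identifiers carry the taxonomy number of cattle as a prefix, as in STRING, a database of known and predicted protein associations. Where the scores came from and how the genes were chosen are not given in the sources used here. If they are STRING scores, as their form would allow, they are database values for pairs of proteins and not measurements on these animals. How a gene of either species was matched to a cattle protein is likewise not given. The gene table used for names, of assembly ARS-UCD2.0, holds no Ensembl identifiers, so 0 genes of the network could be named, and gene identifiers are printed as in the file. The gene lists fixed before the data were examined (fibre type, myogenic regulation, lipid, energy metabolism, matrix, proteolysis, stress, markers of other cell types and known lncRNAs) could therefore not be applied.

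The design fixed before the data were examined was a limma comparison of log2 expression between the species, with tests of those gene lists and of lncRNA and neighbouring gene directions. It needs values per animal, and no expression value was analysed here. The report therefore makes no comparison between cattle and buffalo and gives no p-value for one. The rule for named genes (the largest differences in each direction) had nothing to act on. Loci and genes named in the text were chosen after their values were seen, as loci among the 8 with most listed transcripts or as genes with most partners at some minimum score.

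From the transcript table, the size of each list, the 15 combinations of lists, the overlap of each pair of lists, and the number of listed transcripts per locus were counted. From the gene pairs, the number of partners per gene, connected components and the innermost core (the largest set in which each gene keeps a minimum number of partners) were computed with networkx 3.6.1 at the deposited minimum and at scores of 400, 700 and 900. These analyses used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. Permutation tests used 100000 shuffles, whose smallest possible p is 1e-05. The permutation tests of within-locus agreement and of nearby gene numbers were run on simulated data. Each made a call in 20 of 20 runs with a planted effect (a random 50% of the 2297 loci listed or left out as a whole, or 5% of pairs moved to neighbouring genes among the 3606 genes). Neither made a call in any of 20 runs with no effect. Fewer shuffles were used per run, statuses were drawn at the CNCI rate only, and simulated pairs lacked the network's uneven partner counts. The planted 5% is far above the 0.629% of pairs at 700 or more found with nearby numbers. The runs therefore do not show whether so small a share would be called.

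The read depth of the 6 libraries is unknown here. The counts of transcripts, loci and pairs are complete counts of a table, with no replicates and no sampling error to attach. The counts of transcripts and loci depend on the read depth and on the assembly, which set which transcripts could be found. Whether the counts of pairs do is unknown, since how their genes were chosen is not given. Alternatives tried were dropping 1 list, requiring 3 of the 4 lists, counting loci in other ways and raising the minimum score. In the permutation tests of within-locus agreement and of nearby gene numbers, the loci or pairs used were changed. For gene numbers, how close they had to be was changed as well. The permutation tests of partner counts and of skipped isoform numbers were run in 1 setting only. The alternatives were chosen after seeing the data, since the planned ones concern expression values.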

Results

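The study set out to compare long non-coding RNAs (lncRNAs), transcripts that are not translated into protein, between the muscle of cattle and buffalo. Longissimus muscle was taken from 3 cattle and 3 swamp buffalo, all aged 12 months. The data analysed here are a catalogue of assembled transcripts with 4 coding-potential lists, and a network of gene pairs. Neither has a column for an animal or a species, so neither gives a level in any animal, and no difference between the species could be measured. The transcript and gene names below identify catalogue entries and carry no direction between cattle and buffalo.

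The first question was how far the 4 coding-potential lists overlapped. The catalogue held 21069 transcripts from 15429 loci, and 16236 of them, 77.1%, stood in all 4 lists. A further 3034 transcripts (14.4%) stood in 3 lists, 1095 (5.20%) in 2 and 704 (3.34%) in 1 only. The CNCI list was the longest, with 19682 transcripts, or 93.4% of the catalogue. The CPAT list held 19300 (91.6%), the CPC list 19081 (90.6%) and the Pfam list 18877 (89.6%).

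**Figure D1:**
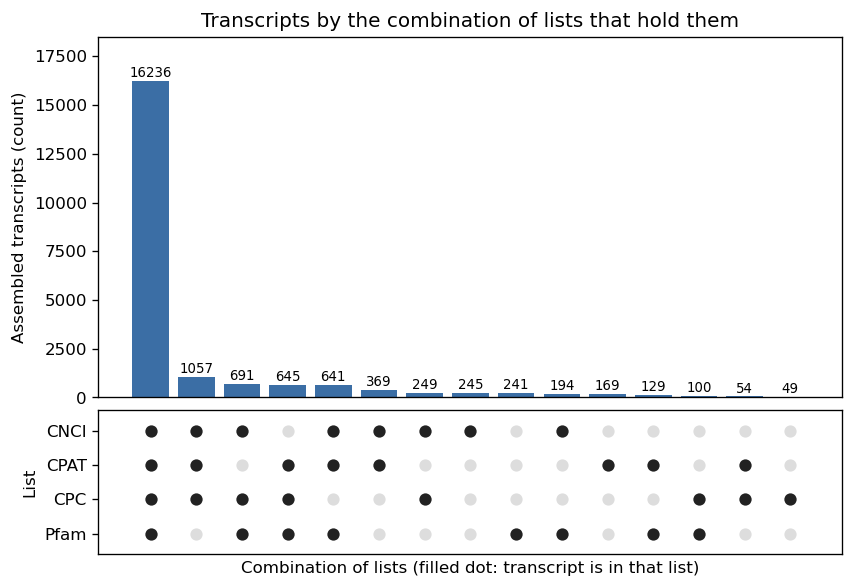
Number of assembled transcripts (bars, linear axis from 0) for each of the 15 combinations of the CNCI, CPAT, CPC and Pfam lists, with filled dots marking the lists that hold the transcripts. The 16236 transcripts in all 4 lists exceed every other combination, and the next bar is the 1057 transcripts missing from the Pfam list alone.

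The domain-based Pfam list differed most from the others. It alone left out 1057 transcripts that the other 3 lists held, against 691 left out by CPAT alone, 645 by CNCI alone and 641 by CPC alone. CNCI and Pfam disagreed on 3035 transcripts (14.4%), the highest number of the 6 pairs of lists, and CNCI and CPC on 2297 (10.9%), the lowest. Transcripts held by a single list numbered 245 for CNCI, 241 for Pfam, 169 for CPAT and 49 for CPC. These are complete counts of the catalogue, so no sampling error applies to them.

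Most loci were represented by 1 transcript. This was so for 13132 loci (85.1%), and the other 2297 loci held 7937 transcripts. In 12603 loci (81.7%) at least 1 transcript stood in all 4 lists, and in 12002 loci every listed transcript did. In 601 loci some transcripts stood in all 4 lists and others did not, and in 2826 loci none did. The mean share of a locus's transcripts in all 4 lists was 81.0% for the 13132 loci with 1 listed transcript and 75.1% for the 1312 loci with 2. It was 70.6% for the 400 loci with 3 and 71.4% for the 585 loci with 4 or more.

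The 8 loci with most listed transcripts were mixed: at 4 of them over 50% of the transcripts stood in all 4 lists, and at the other 4 under 50% did. MSTRG.266192, with 39 listed transcripts the locus with most, had all 39 in the CNCI and Pfam lists, 13 in the CPC list and 2 in the CPAT list, so that 2 stood in all 4. MSTRG.136112 had 35 transcripts, and MSTRG.197498 had 32. At both loci every transcript stood in the CPAT, CPC and Pfam lists and none in the CNCI list, so neither locus has a transcript in all 4. MSTRG.199026 had 35 transcripts, all in the CPC and Pfam lists, 19 in the CPAT list, 6 in the CNCI list and 5 in all 4. MSTRG.246074 had 38 transcripts, of which all stood in the CPAT and Pfam lists, 35 in the CPC list, 31 in the CNCI list and 28 in all 4. In all 4 lists stood 28 of 31 transcripts of MSTRG.215820, 20 of 31 of MSTRG.226887 and 17 of 28 of MSTRG.1538. The positions of these loci in the genome, and the genes next to them, were not analysed here.

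The second data set placed 3606 genes in a network of 207586 gene pairs, which is 3.19% of the 6499815 pairs possible among them. The genes were matched to 3667 cattle proteins: 3520 genes to 1 protein each, and 86 genes to between 2 and 7. Scores ran from 150 to 999 with a median of 212. Scores from 150 to 199 made up 89995 pairs, while 33160 pairs (16.0%) scored 400 or more, 10816 (5.21%) scored 700 or more and 5325 (2.57%) scored 900 or more. The numbers did not fall steadily: 930 pairs scored from 850 to 899 and 3454 from 900 to 949. At 700 or more, 2322 genes (64.4%) kept at least 1 partner, and at 900 or more 1422 genes (39.4%) did. All 3606 genes formed 1 connected network at the deposited minimum. At 900 or more, 1207 genes were still joined in the largest of 79 separate parts, and the next part held 12 genes.

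**Figure D2:**
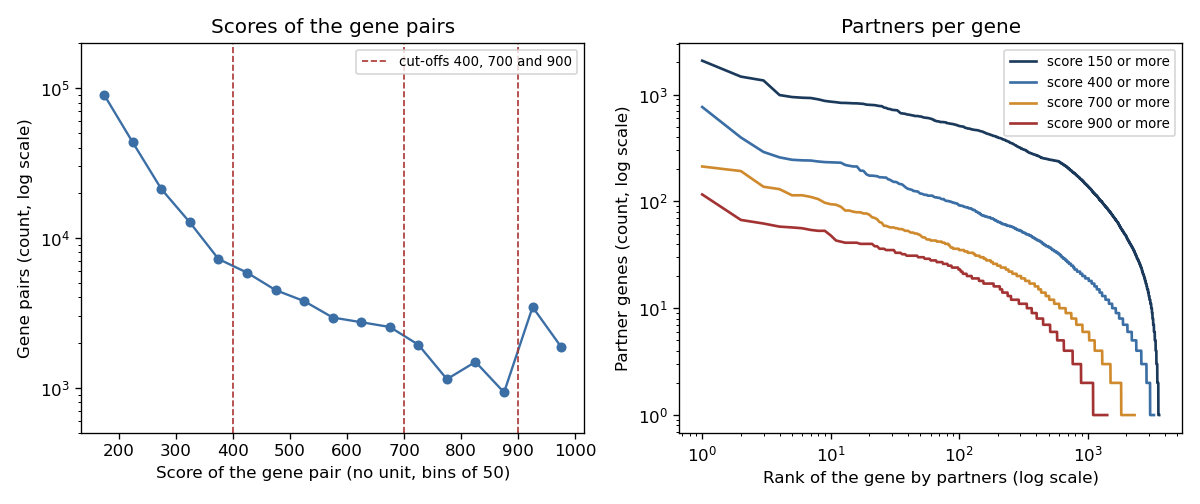
Left, number of gene pairs (log axis) by score, 1 point at the middle of each bin of 50, with dashed lines at 400, 700 and 900. Right, number of partner genes of each gene (log axis) against the gene's rank (log axis), 1 line for each minimum score. The bin from 150 to 199 holds 89995 pairs, and the highest number of partners falls from 2071 partners at a score of 150 or more to 116 at 900 or more.

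Partners were spread unevenly over genes. The median gene had 57 partners, while gene22929 had 2071, or 57.4% of the other genes. It also ranked first at a score of 400 or more, with 764 partners, and at 700 or more, with 212. At 900 or more another gene, gene13776, ranked first with 116 partners. The median there was 4, taken only over the 1422 genes that kept a partner. The 361 genes with most partners, the top 10% of the network rounded up, took part in 65.4% of all pairs. At 700 or more the corresponding 233 genes took part in 65.0% of pairs.

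The most tightly joined group was then picked out at the highest scores. At 900 or more the innermost core consisted of 24 genes, each with at least 20 partners inside the group, and 270 of the 276 possible pairs among them were present. At any score all 276 were present. The group was picked for its many partners inside it, so a high share of present pairs was largely fixed by the selection. No comparison network was made. These 24 genes were matched to 29 proteins, and 4 of them to more than 1. The names and functions of these genes, and whether their expression differed between cattle and buffalo, were not analysed here.

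Repeated protein matches added pairs to the network. The 207586 gene pairs corresponded to 202197 protein pairs, and 4302 protein pairs were listed for more than 1 gene pair, which accounted for 9691 gene pairs. The 57 proteins matched to 2 or more genes, up to 4 genes for 1 protein, gave rise to these repeats. In a repeated pair, the gene on the other side has the same protein association counted once for each gene that shares the protein.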

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

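All alternatives given here were chosen after seeing the data. No paired analysis was possible because the result columns carry no animal and no replicate number, and for the same reason the other settings chosen for expression values before the data were examined (pseudocount, low-value filter, scaling, replicates left out) were not run. The number of transcripts in all 4 lists, 16236, rose to at most 19270 when 3 of the 4 lists sufficed, and to between 16877 and 17293 when 1 list was dropped. The number of loci with such a transcript, 12603, ranged from 10642 to 14463 over its 3 alternatives. The 10642 counts only loci with 1 listed transcript. Each alternative for these counts widens or narrows the same set, so the direction of its change was fixed in advance. The network depended on the minimum score far more: the 207586 pairs fell to 33160 at 400, 10816 at 700 and 5325 at 900. Its 3606 genes fell to 3284, 2322 and 1422, by the construction of the cut-offs. Of 23 alternatives over 9 results, 18 stayed within 1.5 times of the reported count or on the same side of the test. The other 5 did not: the pairs at 400, 700 and 900 and the genes at 700 and 900. Among the 18, the alternatives that widen the set of transcripts or loci could not have failed. For these, 1.5 times the reported count exceeds the whole catalogue of 21069 transcripts or 15429 loci. Depth limits the catalogue, since a transcript too rare to be assembled cannot be listed, and this could not be examined without read counts.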

Other observations

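The tests of this part had their predictions written before their results were seen, except that the pattern of skipped isoform numbers was noticed first and its test designed afterwards. The counts for single scores were also made after seeing the data. For skipped isoform numbers and for partner counts, the written rule was not the one applied, as stated below. The intervals and p-values treat transcripts, loci or genes as the units, which are not replicates of the animals. Transcripts of 1 locus tended to be listed or left out together by a tool. Over the 2297 loci with 2 or more listed transcripts, the mean share of within-locus transcript pairs with the same status was 92.7% for CNCI, 89.1% for CPAT, 93.1% for CPC and 91.6% for Pfam. Shuffling the statuses over the same transcripts gave means of 82.8%, 77.9%, 77.4% and 79.3% (one-sided permutation p = 1e-05 for each tool, the smallest that 100000 shuffles can give). The smallest of the 4 excesses over these loci was 9.82 percentage points, for CNCI. These shuffles mixed loci of all sizes, so a difference in listing rate between small and large loci can add to the excess. The 1312 loci with 2 listed transcripts were therefore also shuffled among themselves. Among them the excess for CNCI was smaller, at 4.66 points (92.6% against a shuffled mean of 87.9%). For the other tools it was 9.32 points for CPAT, 13.2 for CPC and 13.0 for Pfam there (permutation p = 1e-05 for each). This is consistent with isoforms of 1 locus sharing the sequence that the tools judge, so that the 16236 transcripts in all 4 lists may hold fewer independent decisions than their number. Shared sequence itself was not measured.

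Some loci skip isoform numbers: the highest number listed exceeds the number of listed transcripts in 1928 loci, so other isoforms of those loci are in none of the 4 lists or were removed earlier. Among loci with 1 listed transcript, 82.6% of the 11851 without a skipped number had it in all 4 lists, against 67.1% of the 1281 with one, a difference of -15.5 percentage points (95% bootstrap interval -18.2 to -12.8). Loci were then compared at the same highest listed isoform number. The difference was -10.5 points at 2 (interval -14.8 to -6.16), -15.8 at 3 (-23.1 to -8.66) and -11.8 at 4 (-20.5 to -2.67), with two-sided permutation p of 1e-05, 2e-05 and 0.012. The gap is thus present at each of these highest listed numbers. By the rule written for this test, gaps this large at each number would count against a larger number of isoforms as the explanation. That rule was set aside, because isoforms numbered above the highest listed one cannot be seen and the isoform count itself was not held fixed. Whether a larger number of isoforms accounts for the gap therefore stays open. Another candidate explanation, left untested because it needs sequences, is that the skipped isoforms are protein-coding transcripts that share exons with the listed ones. An assembly that joins neighbouring genes into 1 locus stays open in the same way. Some loci counted as complete may not be.

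Genes with nearby numbers in their identifiers were paired more often than shuffled numbers gave. Among the 10816 pairs with a score of 700 or more, 68 pairs, or 0.629%, had numbers within 5 of each other. Shuffling the numbers over the genes gave a mean of 0.0556% and at most 0.176% (one-sided permutation p = 1e-05, the smallest that 100000 shuffles can give). The share was 0.173% among the 174426 pairs under 400, also above its shuffled mean of 0.0556%, and 0.549% at 700 or more among genes and proteins matched 1 to 1. It did not keep rising with the minimum score: at 400 or more it was 0.636%, and at 900 or more it was 0.394% (21 of 5325 pairs). Each of these sets contains the sets at higher minimum scores, so these are cumulative shares. At 400 or more the share rests on 211 of 33160 pairs, which include the 68 of 10816 at 700 or more. Shares in separate score bands were not computed, so where between 400 and 900 the share is highest is not given here. At 700 or more, the share with numbers within 1 was 0.277%, against a shuffled mean of 0.0126%. Within 20 it was 0.971%, against 0.170%. Genes numbered close together may be neighbours on a chromosome, such as members of gene clusters, if the numbers follow the annotation's order. The order was not tested, and 68 of 10816 pairs is a small part of the network.

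Genes matched to 2 or more proteins had a median of 74 partners, against 56 for genes matched to 1. This difference of 18 partners, over 86 and 3520 genes, did not pass a two-sided permutation test (p = 0.13). Whether matching to several proteins raises a gene's own partner count was therefore neither shown nor excluded. The test could not decide this in any case. Protein matches were read from the same pairs, so a gene with more partners had more chances to show several proteins. Part of the difference may come from how the groups were formed. The finding that no repeated protein pair lay between genes matched 1 to 1 follows from the definition and decides nothing.

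The most frequent single score was 158, held by 6038 pairs, against a median of 2337 pairs at the scores within 5 of it. Of these pairs, 4037 (66.9%) included at least 1 of 25 genes that had 100 or more partners at exactly this score. Taken in pairs, these 25 genes shared a median of 87.0% of the partners that either had at this score. At the next most frequent score, 163, held by 4337 pairs, 1028 (23.7%) included at least 1 of 7 such genes, and these shared a median of 14.04% of their partners at that score. The third, 179, was held by 3732 pairs, against a median of 1250 nearby. Of these, 347 (9.30%) included at least 1 of 2 such genes, which shared 88.6% of their partners at that score.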
